A study of Mus musculus with 12 samples.

How the data were processed

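DNA copy number was measured on 12 arrays, each with tumour or liver DNA in Cy3 and liver DNA of a healthy C57BL/6 mouse in Cy5. Per the labels, 10 arrays carry hepatocellular carcinoma (HCC) DNA of AlbLTa/b transgenic mice and 2 carry healthy C57BL/6 liver DNA in both channels. All animals were 18 months old per the labels. The control arrays are called control pair 1 (mice 43415 and 43441) and control pair 2 (mice 43451 and 43457). For these, the mouse named earlier in the title was taken as Cy3, as it is for the tumours; nothing else in the labels gives their order.

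Per the file headers, the 8 scanner files came from Agilent Feature Extraction 9.5.3.1 (protocol CGH-v4_95_Feb07) on array design 015028, with probes placed on mm8 (NCBI36). They hold raw and processed signals as intensity per the file headers, and the authors' Feature Extraction run gave a log10 ratio of Cy5 over Cy3. The processed signals were background-subtracted, detrended and dye-normalised within each array. The deposited value table holds log2 of Cy5 over Cy3 for all 12 arrays. For the 8 arrays with scanner files it equals the scanner ratio on the log2 scale (r at least 0.9996 in each), and the other 4 columns were taken to have the same direction. Partek is named in the submitters' processing notes without a role. Scanner files of the 4 later arrays (C130206_2_b, B130206_2_b, A130206_2_b and C130206_1) were not used here, so these arrays enter no main test.

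For the 8 arrays, log2 of the processed Cy3 over Cy5 signal was taken, spots marked as outliers or not well above background in either channel were removed, and the spots of a probe were averaged. Of 42404 probes, 42027 had a position and a value on all 8 arrays, 40515 on autosomes and 1511 on X. Each array was centred on its autosomal median. Control pair 2 and HCC3 had a negative correlation over all placed probes (r = -0.32). Over autosomal probes alone r was -0.06, and the X medians were 0.82 in control pair 2 and -0.76 in HCC3. The dyes stated in the labels were kept as the direction. The median distance between neighbouring probes was 21.8 kb. Noise between neighbouring probes, as an SD of 1 probe, ran from 0.174 in HCC3 to 0.338 in HCC2. It was 0.220 and 0.205 in the control pairs. No control lies on slide 2, which holds HCC3, HCC4, HCC1c and HCC1d. Slide 1 holds control pair 1 and HCC1a, and slide 3 holds control pair 2 and HCC2. Slide 2 was scanned on another day than slides 1 and 3.

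Autosomes were divided by circular binary segmentation, written for this purpose in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Probes more than 3 SD from the median of 5 neighbours were pulled to that limit. A breakpoint had to exceed a score of 5.26, reached in 1 in 100 of 3040 shuffled chromosomes, with at least 5 probes a segment. Shuffled scores were divided by the SD of the chromosome's values, and scores on the data by the noise between neighbouring probes. In HCC2 the SD over autosomal probes was 0.416 and that noise 0.338. The score could thus be reached more easily in the data than in the shuffles. A segment was called altered at a mean log2 ratio of 0.2 or more from 0. A chromosome was called gained or lost in an array when its median lay 0.1 or more from 0 and beyond every autosomal median of both control pairs. Bins of 1 Mb called the same way in 3 or more of the 6 HCC arrays counted as recurrent, against 1000 rotations of each array's calls around the joined autosomes. The error beside a segment or region, called its SE over probes, is the array's noise between neighbouring probes over the square root of the probe number. Shifts that neighbouring probes share do not enter it, so it can be too small where values vary along a region.

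Gene values are the mean of a gene's probes. Symbols came from the RefSeq gene table of GRCm38.p6 by transcript accession, used for names only. Of 19881 autosomal genes or transcripts, 57 with probes on several chromosomes or over 2 Mb apart were left out and 19824 were tested. HCC and control were compared in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, with the tumour number in the titles (HCC1 to HCC4) as a random block, since HCC1a, HCC1c and HCC1d share one. HCC2 was its own block, though its tissue code (B130206_2_No2) extends that of HCC1d (B130206_2). Whether HCC2 is a separate tumour from HCC1d was not tested. The estimated correlation within a block was 0.379. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists for oncogenes, tumour suppressors, lymphotoxin and NF-kappaB signalling, liver function, the transgene, genes variable between mouse strains and antigen receptor loci were tested with camera at its preset correlation, camera with an estimated correlation, and fry. The members of the antigen receptor list were placed from the array annotation before any value was read. Comparisons of 1 value per array used exact permutation tests, two-sided unless stated, over all 28 splits of 8 arrays; the smallest p they can give is 0.0357.

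Named genes are those of the transgene, genes past the limma threshold with 1 direction in all 6 HCC arrays (up to 10 each way), list members in a recurrent bin or past the threshold over their list, and list members in the 10 widest, 10 highest or 10 lowest altered segments. Not every gene the rule takes is named. Further genes are named as examples of their list or of what lies in a region, and were chosen after their values were seen. The comparisons, tests, gene lists and naming rule were fixed before the data were examined, except where stated.

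The limma comparison was tested on independent Gaussian noise with the residual SD of each real gene, without the correlation within a block. It called 0% of genes shifted by 0.3, 8.33% of those shifted by 0.6 and 61.6% of those shifted by 1, with 1 false call. Segmentation found 85.7% of planted segments of 20 or more probes at a shift of 0.3 and all of them at 0.6. For segments of 10 or fewer probes it found 11.8% at 0.3, 60% at 0.6 and all at 1. There were 4 false calls over the 8 arrays. Probe values were shuffled over the autosomes for this, so calls from shifts that neighbouring probes share are not counted. In the real data control pair 2, healthy against healthy, had 38 altered segments.

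Alternatives were other background correction (normexp in limma, offset 50), other centring, no filter on dim probes, the deposited value table for 8 or 12 arrays, other limits for segments, bins and chromosomes, other blocks, HCC against 0, and leaving out each array. A correction that regresses each array on the running median of control pair 2 over 51 probes, slide as a fixed block, leaving out HCC1a, HCC2 and HCC1d together, and HCC1 arrays averaged for the altered share were added after the data were seen. A correction on the GC content of the probes was planned and not run, as probe sequences were not used here.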

Results

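The arrays compared tumour DNA of AlbLTa/b mice, which carry lymphotoxin alpha and beta transgenes driven in the liver, with liver DNA of age-matched C57BL/6 mice. The labels name 10 HCC arrays and 2 control arrays of healthy against healthy liver. The main comparisons use 6 HCC arrays (HCC1a, HCC1c, HCC1d, HCC2, HCC3 and HCC4) and both control pairs; 4 later HCC arrays enter the repeats alone. Median background-subtracted Cy3 signal was 30.2 in HCC2, 31.8 in HCC1a, 32.6 in HCC1d and 36.0 in HCC1c. It was 54.9 in HCC3, 65.1 in HCC4, 70.0 in control pair 1 and 71.2 in control pair 2. The number of arrays limits the precision of every group comparison. All positions are on mm8, and ratios are log2 of tumour over reference.

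How much of the genome is altered in these tumours was asked of the autosomes. HCC4 carried long, well separated gains and losses, among them a gain over Mdm2 and Cdk4 and a loss over most of chromosome 4. HCC1c carried a high-level gain around Cdk6, and HCC3 a gain of chromosome 14. Altered segments covered 19.6% of the autosomes in HCC1a, 20.03% in HCC2, 17.2% in HCC1c, 13.7% in HCC4, 5.27% in HCC3 and 1.68% in HCC1d. They covered 0.0429% in control pair 1 and 2.91% in control pair 2. The mean was 12.9% ± 7.74 (SD, n = 6) in HCC and 1.47% ± 2.02 (SD, n = 2) in control, a difference of 11.4 percentage points that did not pass the exact permutation test (two-sided p = 0.107, with 0.0357 the smallest possible). Within slide 1 the HCC array exceeded its control by 19.6 points, and within slide 3 by 17.1; slide 2 has no control. Without HCC1d the difference was 13.7 points and passed (exact permutation p = 0.0476, the smallest possible there). HCC1d was the only HCC array with a lower share than control pair 2, so leaving it out gives that smallest p. These tests count HCC1a, HCC1c and HCC1d apart, though they share a tumour number; averaged to 1 value the difference was 11.5 points (exact p = 0.133, with 0.0667 the smallest possible). After regression on control pair 2 the difference was 2.39 points, with control pair 2 itself left uncorrected; with normexp it was 0.514 points. That regression left 0.3% in HCC1a, 2.07% in HCC2, 0.648% in HCC1c and 1.32% in HCC1d, against 13.5% in HCC4 and 5.34% in HCC3. The share counts only what passes the 0.2 limit: HCC1c kept all 6 of its chromosome calls, and stood at r = 0.783 with C130206_2_b with control pair 2 regressed out.

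**Figure D1:**
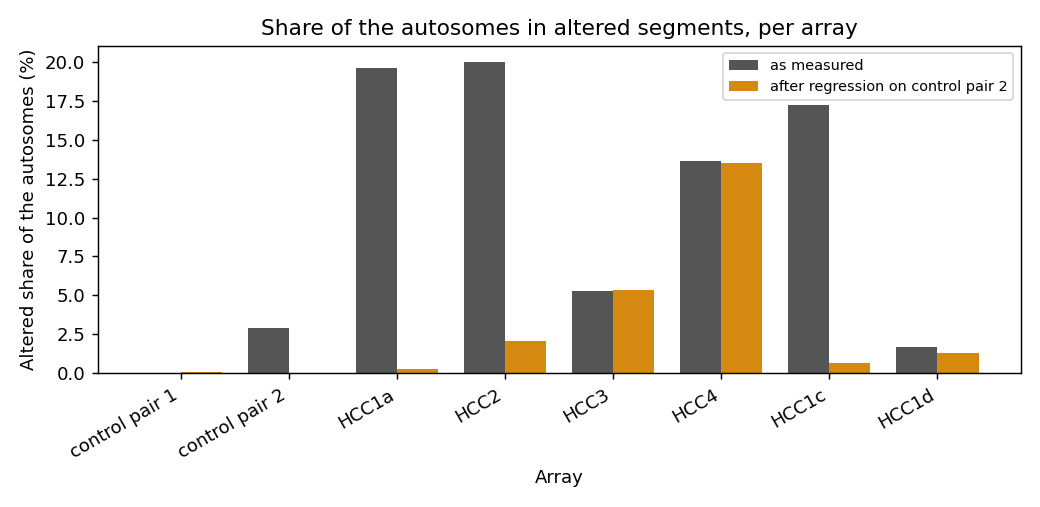
Percent of the autosomes in altered segments, 1 array per position. Grey bars are the values as measured and orange bars those after regression on control pair 2, which has no orange bar of its own. HCC4 stays at 13.5% and HCC3 at 5.34%, while HCC1a goes from 19.6% to 0.3%.

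HCC4 held 31 altered segments, 21 gained and 10 lost. This count includes short losses with the same ends in HCC3, on chromosomes 9 (46630511 to 46764214) and 17 (26922391 to 27237228). There control pair 2, healthy against healthy, stood at 0.53 and 0.66, so these are not shown to be tumour changes. A segment on chromosome 6 (60656416 to 60917980) also recurred with the same ends, at 0.93 in HCC4, 0.85 in HCC1c and -0.85 in HCC3. Proximal chromosome 17 (3075728 to 19817230) had a mean log2 ratio of 0.59 ± 0.01 (SE over 186 probes) and holds Arid1b and Igf2r, a receptor that clears Igf2. The gene value of Igf2r was 0.97 and that of Arid1b 0.53. A further gain on chromosome 17 (41779471 to 62209428, 0.51 ± 0.01) holds Vegfa, C3 and Tnfsf14, with gene values of 0.63, 0.65 and 0.75 (Tnfsf14 from 1 probe). On distal chromosome 10 (114209207 to 129759311, 0.53 ± 0.01), Mdm2, which restrains p53, stood at 0.67 and Cdk4, a kinase of the G1 phase, at 0.67 from 1 probe. Gains also covered Rictor on chromosome 15 (3229082 to 13096313, 0.51 ± 0.01), Fgfr1 and Ikbkb on chromosome 8 (6221264 to 28693714, 0.39 ± 0.01), and Yap1 and Birc3 on chromosome 9 (4296127 to 10251674, 0.26 ± 0.02). Chromosome 4 was lost from 43680693 to 119043284 at -0.30 ± 0.01 over 1089 probes, a span with Cdkn2a, Jun and the Skint genes. Its neighbour (3933729 to 42952781) was lost at -0.34 ± 0.01. Distal chromosome 13 (64148069 to 120604804), with Tert and Nnt, was lost at -0.33 ± 0.01; the gene values were -0.39 and -0.31.

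HCC1c held 35 altered segments, 16 gained and 19 lost. The segment furthest from 0 lay on proximal chromosome 5 (3285647 to 4809538) at 2.00 ± 0.05 over 34 probes, a linear ratio of 4.0. It holds Cdk6, a partner of D-type cyclins in the G1 phase, together with Fam133b, Gatad1, Krit1, Akap9 and Cyp51. Cdk6 had a gene value of 1.95 there, against 0.03 to 0.21 in the other 5 HCC arrays and 0.15 and 0.03 in control pairs 1 and 2. Across the whole segment the other HCC arrays lay between -0.14 and 0.02, and control pairs 1 and 2 at 0.00 and -0.09. Further along chromosome 5 (40054885 to 108366337), a loss of -0.22 ± 0.01 covered Alb, Afp, Cxcl1, Cxcl10 and Cxcl13. Losses also covered parts of chromosomes 4 (62999402 to 105939282, -0.28 ± 0.01), 13 (61009908 to 120604804, -0.21 ± 0.01) and 16 (45668049 to 89676040, -0.27 ± 0.01). Gene values within them went both ways, with Cdkn2a at -0.78 and Jun at 0.10 on chromosome 4, and Tert at 0.25 and Nnt at 0.27 on chromosome 13. After regression on control pair 2, 9 altered segments were called in HCC1c; the Cdk6 gain stayed. The 4 wide losses then averaged -0.21 on chromosome 4, -0.18 on 5, -0.17 on 13 and -0.19 on 16 (SE 0.01 each). On chromosomes 5, 13 and 16 the spans were then themselves under the 0.2 limit, while the span on chromosome 4 stayed past it. All 4 lay within a segment over most of their chromosome, at -0.16 to -0.17, and were no longer called.

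**Figure D2:**
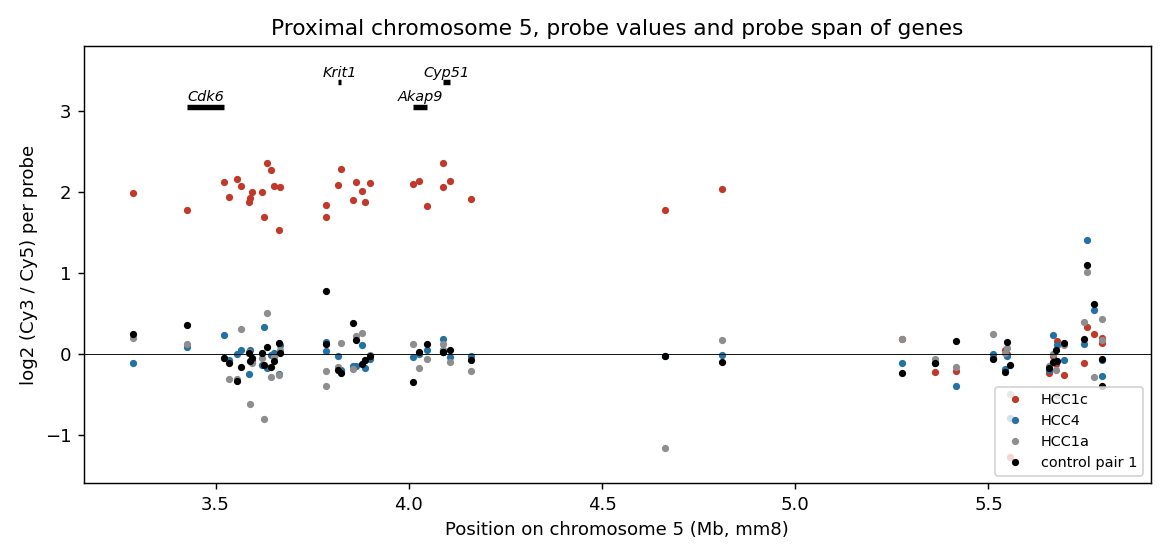
Log2 ratio of each probe on proximal chromosome 5, by position in Mb (mm8), for HCC1c, HCC4, HCC1a and control pair 1. Black bars mark the span of the probes of 4 genes. The 34 probes of HCC1c from 3285647 to 4809538 average 2.00, and the next segment of HCC1c (5277435 to 22187369) averages -0.30.

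HCC3 held 42 altered segments, 18 gained and 24 lost, most of them short. Chromosome 14 was gained in 3 adjoining segments, at 0.21 ± 0.01 (6628547 to 21882778), 0.20 ± 0.01 (23453177 to 68535910) and 0.30 ± 0.02 (68568009 to 74846158). Its tumour suppressors Fhit, Lats2 and Rb1 lay in gained segments, as did Entpd4. Part of distal chromosome 3 (138436597 to 159870361) was lost at -0.20 ± 0.01. HCC2 and HCC1d, of tissue codes B130206_2_No2 and B130206_2, shared a loss on chromosome 5 between 13823804 and 42120796. It stood at -0.35 ± 0.01 in HCC2 and -0.24 ± 0.01 in HCC1d over 531 probes. It spans Hgf, a growth factor for hepatocytes, and Il6. The same span stood at 0.03 in HCC1a and HCC3, 0.00 in HCC4, -0.14 in HCC1c and 0.03 in both control pairs. Around Hgf, however, HCC1a (8451141 to 19577477, -0.34 ± 0.03) and HCC1c (5277435 to 22187369, -0.30 ± 0.02) were called lost too. After regression on control pair 2 only HCC2 and HCC1d held a segment past the 0.2 limit there. HCC1c then had a segment from 5277435 to 151918350 at -0.16 ± 0.005, and its chromosome 5 stayed called lost at -0.13. HCC1a held 81 altered segments, HCC2 77 and HCC1d 13, against 2 in control pair 1 and 38 in control pair 2. The mean was 46.5 in an HCC array. Regression on control pair 2 left 16 in HCC1a, 11 in HCC2 and 4 in HCC1d, but 27 in HCC4 and 45 in HCC3.

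**Figure D3:**
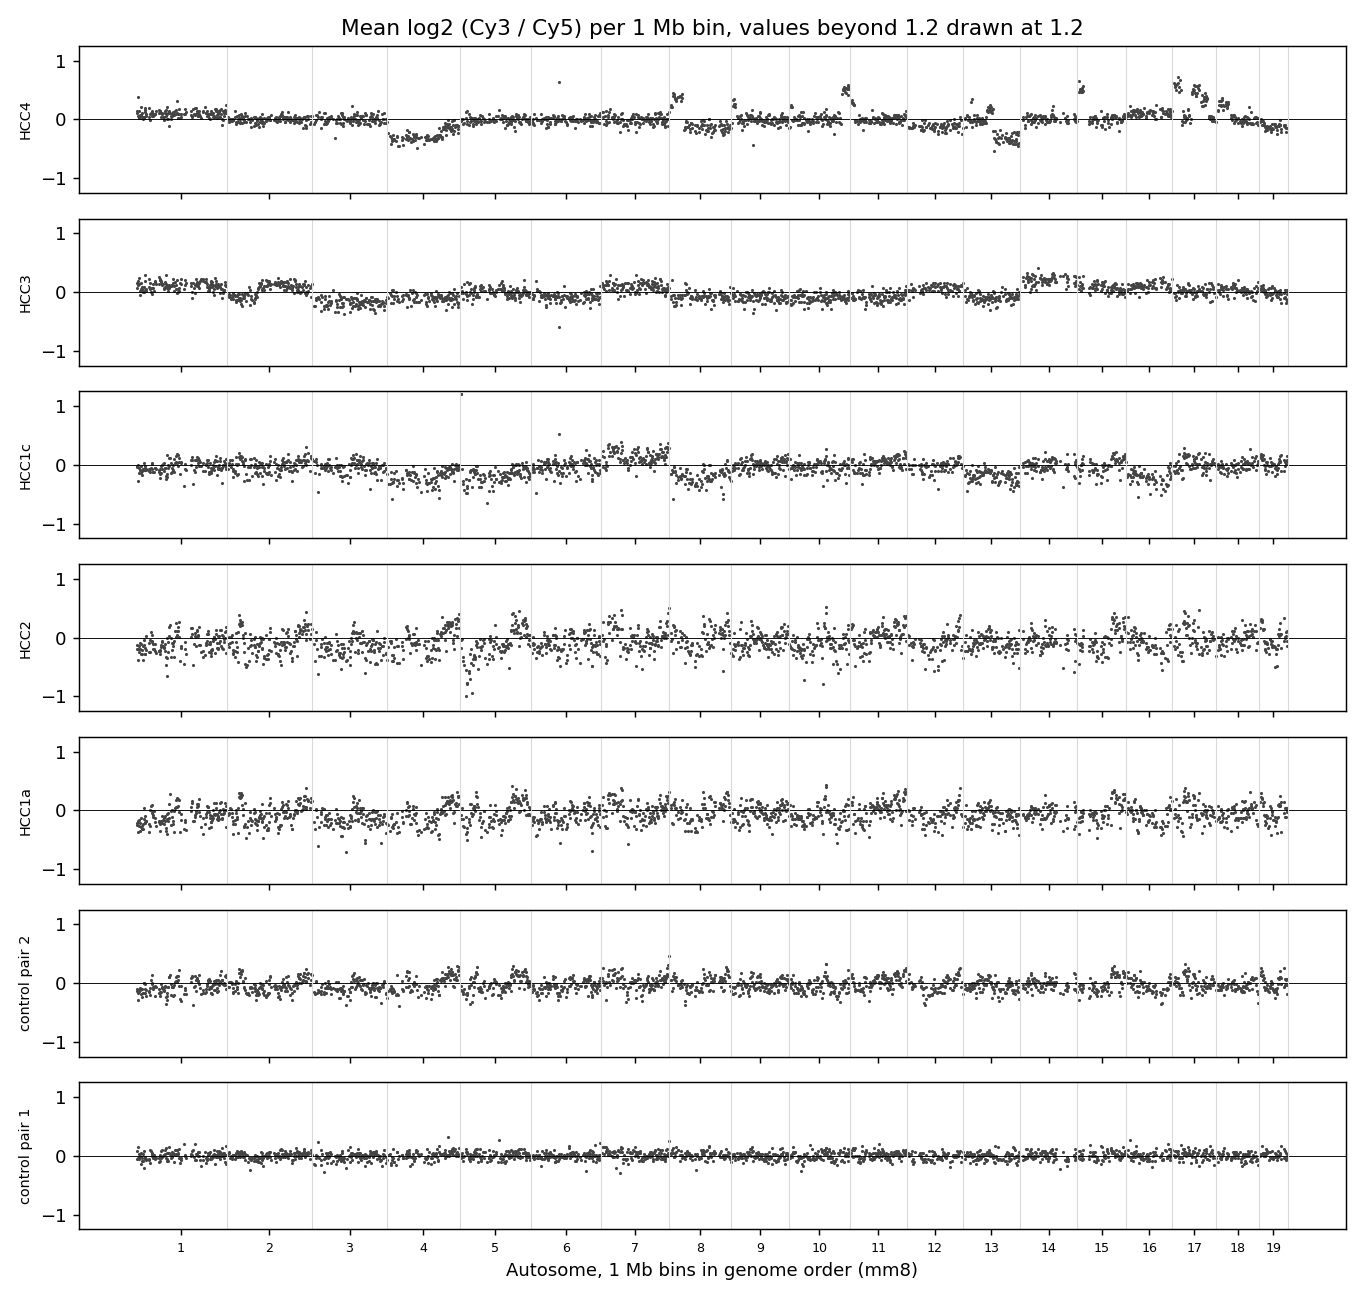
Mean log2 ratio per 1 Mb bin along the autosomes (mm8) for 5 HCC arrays and both control pairs, with grey lines between chromosomes. HCC4 shows steps such as chromosome 4 (median -0.25) and chromosome 17 (median 0.22), HCC3 a raised chromosome 14 (median 0.21), and HCC1a and HCC2 a fine wave that control pair 2, which has the same reference mouse, shows too (r = 0.82 and r = 0.81).

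Gain or loss at the level of a chromosome was called 17 times among 114 chromosome medians of the HCC arrays. The limit of 0.1 decided the calls, since the control median furthest from 0 was 0.06 in size. HCC4 had 6 calls, with chromosome 17 at 0.22 and 16 at 0.11 gained, and 4 at -0.25, 12 and 13 at -0.12 and 19 at -0.11 lost. HCC1c also had 6, with chromosome 7 gained at 0.20 and chromosomes 4, 5, 8, 13 and 16 lost at -0.12 to -0.16. HCC3 had 4 calls, with chromosomes 1 (0.11), 7 (0.10) and 14 (0.21) gained and chromosome 3 (-0.16) lost. HCC2 had a gain of chromosome 11 at 0.11, and HCC1a and HCC1d had 0 calls. Of 19 autosomes, 0 had an unadjusted p under 0.05 between HCC and control (exact permutation test; lowest adjusted p = 0.679, where no single autosome could pass after adjustment). Of the calls, 7 were gains and 10 losses; with no further centring 11 were gains and 6 losses, so that balance depends on the centring. After regression on control pair 2, 16 of the 17 calls stayed; chromosome 11 of HCC2 moved to 0.02, and chromosome 1 of HCC4 (0.10) was newly called. With normexp far fewer calls were made.

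**Figure D4:**
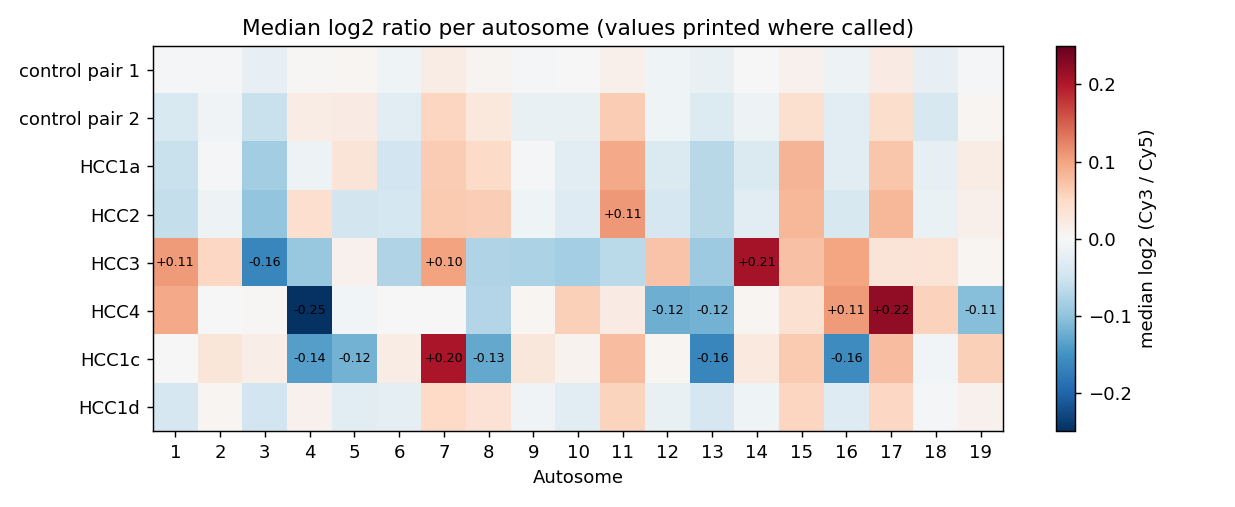
Median log2 ratio of each autosome in the 8 arrays, red above 0 and blue below; called chromosomes carry their value. Calls concentrate in HCC4, HCC1c and HCC3, and chromosome 4 of HCC4 has the lowest at -0.25.

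Whether the tumours share altered regions was asked in 1 Mb bins. Losses on chromosome 4, in 77 bins that include Cdkn2a, Jun, Cyp7a1 and the Skint genes, and on chromosome 8, in 28 bins, made up most of the recurrent losses. Gains on chromosome 7, in 25 bins that include Ccnd1, Hras, Igf2 and Akt2, made up most of the recurrent gains. Control pair 2, healthy against healthy, was itself called gained on chromosome 7 from 140700507 to 145131345 (0.20). That span holds Ccnd1, Hras and Igf2, whose gene values in control pair 2 were 0.01, 0.79 and 0.37. Gains there are therefore not shown to be particular to tumours. In all, 166 of 2176 bins were recurrent, 43 gained and 123 lost, and up to 5 arrays shared a bin (p = 0.00899 by the rotation test, a permutation of positions). Rotations gave a median of 18 recurrent bins, and none reached 166 (permutation p = 0.001, the smallest 1000 rotations can give). The rotations treat HCC1a, HCC1c and HCC1d as independent, though they share a tumour number, and HCC2, which shares part of its code with HCC1d. These p therefore do not speak for separate tumours. Control pair 2 was called in 23 of these bins and control pair 1 in 0. After regression on control pair 2, 0 bins were recurrent. Without HCC1a, HCC2 and HCC1d 3 bins were, but there a bin had to be called in all 3 arrays left. The calls in these bins went from a mean size of 0.24 to 0.06 in HCC1a, 0.30 to 0.10 in HCC2, 0.28 to 0.11 in HCC1d, 0.30 to 0.20 in HCC1c, 0.33 to 0.31 in HCC4 and 0.22 to 0.22 in HCC3.

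Gene by gene, 1 transcript differed between HCC and control. AK155119 on chromosome 11 (116570620 to 116571580, 3 probes) was lower by a log2 difference of -1.45 ± 0.15 (SE), in 6 of 6 HCC arrays (limma, adjusted p = 0.00288). Its mean was -1.38 ± 0.12 (SD, n = 6) in HCC and 0.07 in control (n = 2). Within slides 1 and 3 the difference was -1.33 and -1.47. With slide as a fixed block it was -1.40 and missed the threshold (limma, adjusted p = 0.0585). Without control pair 2, which leaves 1 control array, it was -1.34. With normexp it missed the threshold too. No gene was higher; 1001 of 19824 genes had an unadjusted p under 0.05 in limma. Vegfa, an angiogenic factor, and Ccnd1, which encodes cyclin D1, stood above both control pairs in 6 of 6 HCC arrays without passing, at 0.45 ± 0.16 and 0.36 ± 0.14 (SE; adjusted p = 0.977 for each, Ccnd1 from 1 probe). Cdkn2a, the cell cycle inhibitor locus, stood at -0.43 ± 0.28 (SE; adjusted p = 0.985).

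None of the gene lists passed, and no member of any list passed adjusted over the list alone. Of 39 oncogenes measured, 28 had a difference above 0 and 0 passed over all genes tested. In at least 1 HCC array, 19 lay in a gained segment and 4 in a lost one. Array by array, 9 were gained in HCC1a, 10 in HCC2, 8 in HCC1c, 7 in HCC4, 1 in HCC3 and 0 in HCC1d. Control pair 2 had 5 in gained segments and control pair 1 had 0. Of the tumour suppressors, 17 lay in a gained segment of at least 1 HCC array and 3 in a lost one. The share of all genes in such segments was not set beside these counts, so they show nothing particular to a list. Beside Vegfa and Ccnd1, Myc stood 0.33 higher in HCC, from 1 probe. The list averaged 0.09 above control (camera adjusted p = 0.0625; adjusted p = 0.464 with an estimated correlation; fry adjusted p = 0.461), and within slides 1 and 3 it averaged 0.08 in each. It passed camera with the HCC1 arrays averaged (adjusted p = 0.0382) and without HCC1a, HCC2 and HCC1d (adjusted p = 0.0216), neither of which held with an estimated correlation (adjusted p = 0.217 and 0.281); leaving out control pair 1, HCC2 or HCC1d alone also took camera past the threshold (adjusted p = 0.0302, 0.0383 and 0.0262; adjusted p = 0.525, 0.541 and 0.134 with an estimated correlation). Of 37 tumour suppressors, 20 stood above 0, with Arid2 at 0.30 and Socs3 at 0.39, and the list averaged 0.03 (camera adjusted p = 0.645), with 0.04 within slide 1 and -0.04 within slide 3. Among 28 genes of lymphotoxin and NF-kappaB signalling, 15 stood above 0. Tnfrsf1a, the TNF receptor, was at 0.30, and Traf3, which restrains non-canonical NF-kappaB signalling, at -0.38. The mean of that list was -0.0029, while its median (0.02) and its test pointed up (camera adjusted p = 0.760); within slides 1 and 3 it was -0.04 and 0.0037.

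Of 22 liver function genes, 12 stood above 0, with Apoa1 at 0.16 and Fgg at -0.27, and the list averaged 0.01 (camera adjusted p = 0.645), but -0.12 within slide 1 and -0.019 within slide 3. Of 16 genes variable between mouse strains, 6 stood above 0, with Skint9 at 0.31 and Btbd9 at -0.25. In at least 1 HCC array, 11 lay in a lost segment. Array by array, 10 were lost in HCC1a, 6 in HCC4, 6 in HCC1c, 2 in HCC2, 1 in HCC1d and 0 in HCC3. Control pair 2 had 1 and control pair 1 had 0. The list averaged -0.04 (camera adjusted p = 0.645), with -0.24 and -0.03 within slides 1 and 3. Of 9 antigen receptor transcripts, which lose DNA in rearranged lymphocytes, 3 stood above 0 and the list averaged -0.06 (camera adjusted p = 0.645), with -0.18 and -0.11 within slides 1 and 3. Its array means were -0.16 in HCC1a, -0.18 in HCC2, -0.13 in HCC1d, -0.05 in HCC1c, -0.02 in HCC4 and 0.00 in HCC3, against 0.02 and -0.08 in control pairs 1 and 2.

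The transgene genes Lta and Alb were tested because AlbLTa/b mice carry added lymphotoxin DNA. Lta on chromosome 17 (34811452 to 34811511, 1 probe) had a mean of 0.60 ± 0.28 (SD, n = 6) in HCC and 0.47 in control, a limma difference of 0.14 ± 0.20 (SE; adjusted p = 0.994, and 0.783 adjusted over the list alone). It lay above both control pairs in 4 of 6 HCC arrays. Within slides 1 and 3 the difference was 0.16 and 0.63. Alb on chromosome 5 (91536940 to 91547904, 2 probes) differed by 0.06 ± 0.21 (SE; limma adjusted p = 0.994), with -0.41 within slide 1 and 0.00 within slide 3. The list of both averaged 0.10 (camera adjusted p = 0.645), with -0.13 and 0.32 within slides 1 and 3. Ltb had no probe among the genes tested.

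Whether the arrays that share tumour number HCC1 are more alike than others was tested on their profiles. Over 1868 bins, HCC1a and HCC1d correlated at 0.77, HCC1a and HCC1c at 0.54, and HCC1c and HCC1d at 0.54; bins are not independent replicates. The mean was 0.617 within HCC1 and 0.249 over the other pairs, a difference of 0.368 that did not pass (exact one-sided permutation p = 0.2 over 20 choices of 3 arrays; the smallest possible is 0.05, so it could not fall below the threshold). HCC2 has another number, but its code (B130206_2_No2) extends that of HCC1d (B130206_2). It correlated at 0.84 with HCC1a and 0.81 with HCC1d, which is not shown to be likeness between separate tumours. Control pair 2, healthy against healthy, correlated at 0.82 with HCC1a, 0.81 with HCC2, 0.67 with HCC1d and 0.42 with HCC1c. These likenesses are therefore not shown to come from tumour changes alone. After regression on control pair 2 the mean was 0.445 within HCC1 and 0.209 over the other pairs. That difference of 0.237 did not pass either (exact one-sided permutation p = 0.2). On slide 2 alone, HCC1c and HCC1d had 0.54 and the pairs with HCC3 or HCC4 ran from -0.01 to 0.23. Codes A130206_2, B130206_2 and C130206_2 recur among the later arrays, and the first and later array of a code correlated at 0.641 on average (0.454 to 0.740, 3 pairs), against 0.456 over 42 other pairs. With control pair 2 regressed out these were 0.398 and 0.333. HCC2 was counted as another code, so the 42 other pairs include HCC2 with HCC1d and with B130206_2_b, at 0.804 and 0.797. With control pair 2 regressed out those pairs stood at 0.617 and 0.494. The comparison therefore depends on how HCC2 is counted. The Cdk6 gain of HCC1c, of code A130206_2, stood at -0.34 ± 0.07 in the later array A130206_2_b and at 1.90 ± 0.06 in C130206_2_b.

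**Figure D5:**
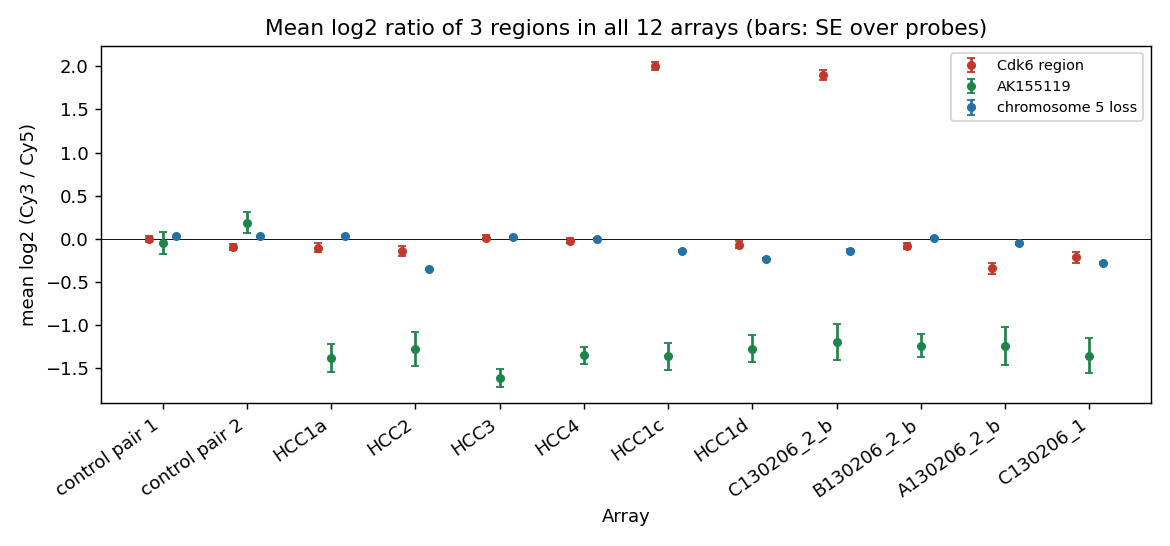
Mean log2 ratio of 3 regions in all 12 arrays, with bars for the SE over probes. The Cdk6 region stands at 2.00 in HCC1c and 1.90 in C130206_2_b, and AK155119 lies below -1 in every HCC array. The chromosome 5 loss stands at -0.35 in HCC2, -0.24 in HCC1d and -0.28 in C130206_1, with HCC1c and C130206_2_b at -0.14 each.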

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

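The tests in this part were chosen after the results were seen, apart from that of local probe density, whose bounds were set beforehand. Single arrays were set against the other 5 HCC arrays by the gap to the nearest value over the whole range, for 64 sets of values, of which 9 stood apart. Chance gives about 1 in 20 for sets picked without regard to their values; the Cdk6 region and part of the genes were picked for extreme values, and Cdk6 counts as region and as gene, so the 9 are not compared with chance. For chromosome medians these were HCC3 on chromosome 9 (-0.079) and 14 (0.21), and HCC4 on chromosome 17 (0.22) and 19 (-0.11). For regions and genes they were HCC1c over the Cdk6 region (2.00) and Cdk6 itself (1.95), HCC4 at Igf2r (0.97), HCC3 at Alb (0.36) and HCC3 at AK155119 (-1.61, with the others from -1.38 to -1.27). The later arrays, which no main comparison uses, each held segments beyond the 0.2 limit. Only segments of 20 or more probes that overlap no altered segment of a control pair were ranked. Among these, furthest from 0 were chromosome 5 in C130206_2_b (1.90 ± 0.06), chromosome 7 in B130206_2_b (-0.31 ± 0.04), chromosome 8 in A130206_2_b (-0.60 ± 0.07) and chromosome 5 in C130206_1 (-0.52 ± 0.03, SE over probes). Smaller stretches were left out by this rule. AK155119, of 3 probes, stood at -1.24 in B130206_2_b, -1.24 in A130206_2_b and -1.35 in C130206_1.

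Later arrays carried other changes than the first array of their tissue code: the Cdk6 gain of HCC1c, of code A130206_2, was missing in A130206_2_b and present in C130206_2_b. Noise of the later arrays is argued against by the difference of 2.34 ± 0.08 (SE) between HCC1c and A130206_2_b over that region. An exchange of codes between the deposits may account for the Cdk6 gain: C130206_2_b correlated at 0.783 with HCC1c, control pair 2 regressed out. A130206_2_b and B130206_2_b correlated best with HCC1a (0.463 and 0.589) and C130206_1 with HCC2 (0.660), so which codes such an exchange would join stays open. Pieces of 1 tumour that differ in copy number cannot be told apart from such an exchange, because the Cdk6 segment ends 0 kb apart in both arrays, as either would give, and no label says which piece a code stands for.

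HCC1d is labelled with reference mouse 43451, as is HCC3, yet the X median was -0.02 in HCC1d and -0.76 in HCC3. In control pair 2, mouse 43451 over 43457 gave an X median of 0.82 and a Y probe at -2.95, the values of a female over a male. The sex of the animal behind HCC1d is argued against by loci on chromosomes 9 and 17, where control pair 2 averaged 0.59 and HCC1d minus HCC2 was 0.042 ± 0.14 (SE), not about 0.59 lower; this takes both tumours to share those loci, as their codes do in part. A wrong reference label may account for HCC1d: its X median differed by 0.011 from that of HCC2, which was set against mouse 43457. The later 4 arrays carry the same reference label and had X medians of -0.08 to 0.03.

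HCC1a and HCC2 followed control pair 2, with which they share reference mouse 43457 in Cy5, along the genome (r = 0.82 and r = 0.81); HCC1d and HCC1c, labelled with other reference mice, had r = 0.67 and r = 0.42, and HCC4 r = 0.08. Copy number changes of the tumours alone are argued against for the calls of HCC1a and HCC2 in recurrent bins, which kept 25.1% and 32.5% of their mean size after regression on control pair 2, where changes unrelated to it would stay. A wave as the whole cause is argued against for the calls of HCC1c and HCC4, which kept 68.1% and 93.5%; HCC1d, at 40.4%, was left undecided. For HCC1a and HCC2 a wave that control pair 2 carries too may account for the larger part, and local probe density, a stand-in for base composition, may be part of it: bin means correlated with it at 0.506 in HCC1a, 0.515 in HCC2, 0.424 in HCC1d, 0.329 in HCC1c and 0.499 in control pair 2, against 0.148 in control pair 1, 0.104 in HCC3 and 0.076 in HCC4, across bins, which are not independent. GC content itself was not tested, and the shared reference DNA, which regression on control pair 2 would remove too, stays open as untested.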

How the results depend on the processing

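The regression on control pair 2, slide as a fixed block, leaving out HCC1a, HCC2 and HCC1d together, and averaging HCC1 arrays for the altered share were chosen after the data were seen; the other alternatives were fixed before. A GC correction was not run. Where a value moved, the cause was not tested. The altered share kept its direction in all 22 alternatives and stayed short of the threshold in 21; without a control pair, without HCC1a, HCC2 and HCC1d, or with HCC1 arrays averaged (11.5 points) it could not pass. It was 2.39 points after regression on control pair 2, which was itself left uncorrected, and 0.514 with normexp. At limits of 0.1 and 0.3 it was 22.9 and 3.57. Leaving out single arrays gave 10.01 to 13.7 points, highest without HCC1d (exact permutation p = 0.0476, the smallest possible there). Profile similarity within HCC1 kept its direction in all 12; its test was too small to pass.

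Altered segments per HCC array numbered 14.5 with normexp, 18.7 after regression on control pair 2, 94.7 at a limit of 0.1 and 21.3 at 0.3. Recurrent bins numbered 103 with no further centring, 0 with normexp, 0 after regression on control pair 2, 915 and 9 at limits of 0.1 and 0.3, 290 and 91 with bins of 0.5 and 2 Mb, 422 in 2 or more tumour numbers, 3 without HCC1a, HCC2 and HCC1d, and 67 to 166 leaving out single arrays (67 without HCC1a, 103 without HCC2, 75 without HCC1c). Without HCC1a, HCC2 and HCC1d a bin had to be called in all 3 arrays left. Chromosome calls numbered 3 with normexp, 43 and 4 at limits of 0.05 and 0.2, and 11 to 17 leaving out single arrays (11 without HCC4 or HCC1c).

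Genes higher in HCC numbered 115 against 0 in place of the controls, and 0 to 1 leaving out single arrays (Cadm4 without HCC1a, Serpina1f without control pair 2). Genes lower numbered 13 against 0, 0 with normexp, 0 with slide as a fixed block, and 0 to 2 leaving out single arrays (AK087220 joins without control pair 1; AK155119 drops out without control pair 2). AK155119 kept its direction throughout, at -1.31 with normexp (adjusted p = 0.432) and -1.57 to -1.34 leaving out single arrays. Gene lists past the threshold numbered 1, the oncogenes, with HCC1 arrays averaged, 1 without HCC1a, HCC2 and HCC1d, and 0 to 1 leaving out single arrays (without control pair 1, HCC2 or HCC1d); with an estimated correlation none passed (adjusted p = 0.217, 0.281, 0.525, 0.541 and 0.134).

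Lta turned to -0.057 with normexp, -0.012 after regression on control pair 2 and -0.051 without HCC1a, HCC2 and HCC1d, and passed at 0.61 against 0 (adjusted p = 0.0412); leaving out single arrays gave 0.03 to 0.25. Alb turned to -0.027 with the value table of 12 arrays, -0.21 with slide as a fixed block, -0.14 against 0, -0.081 without the HCC arrays set against mouse 43451, and ran from -0.16 to 0.28 leaving out single arrays (-0.16 without control pair 2, -0.08 without HCC3). Repeats of a code correlated at 0.398 with control pair 2 regressed out. Without a control pair, the other is taken to vary like the HCC arrays. Of simulated segments of 10 or fewer probes, 11.8% were found at a shift of 0.3 and 60% at 0.6, so small shifts over few probes are often missed. Signal was 0.576 to 1.13 times background in Cy3 of the HCC arrays; its effect on this was not tested.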

Other observations

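The tests in this part were chosen after the results were seen. Cdkn2a, the locus of the p16 and Arf inhibitors, had 2 probes with low values in 4 HCC arrays. They stood at -1.29 in HCC1d, -1.01 in HCC2, -0.78 in HCC1c and -0.77 in HCC1a, against -0.15 in HCC4, -0.06 in HCC3, and -0.06 and -0.28 in control pairs 1 and 2. These 4 arrays also had the lowest Cy3 signal (30.2 to 36.0, against 54.9 to 71.2) and the steepest slopes on control pair 2 (0.70 to 1.46, against -0.015 in HCC3 and 0.17 in HCC4). The chromosome 5 loss over Hgf and Il6 in HCC2 and HCC1d stood at -0.28 ± 0.02 (SE over 531 probes) in the later array C130206_1. It stood at -0.14 in C130206_2_b, -0.05 in A130206_2_b and 0.02 in B130206_2_b. C130206_2_b had 7 chromosome calls, with chromosomes 7 (0.13), 11 (0.15) and 17 (0.12) gained and 4, 5, 13 and 16 lost at -0.10 to -0.19. These medians were not regressed on control pair 2, with which C130206_2_b correlated at 0.66. In HCC2 such regression took chromosome 11 from 0.11 to 0.02.

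AK155119 lay low in every HCC array, later ones included, the highest being -1.19 ± 0.21 (SE over 3 probes), while control pairs 1 and 2 stood at -0.05 and 0.19. A variant carried by the transgenic line is a candidate explanation, as a hypothesis found in these data. No healthy DNA of the line was used here, so it is not separated from a loss in every tumour.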
